A study of Capra hircus with 6 samples.

How the data were processed

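Total RNA of goat fetal fibroblasts was depleted of ribosomal RNA and made into stranded Illumina libraries read for 150 cycles, per the labels' protocols. The labels give 2 groups of 3 libraries, cells exposed to 0.5 µg/mL GO-AgNP for 10 weeks and cells exposed to 0 µg/mL, passaged every 2 to 3 days. Groups were taken from the labelled treatment and each table column from its heading, which is the title of its sample.

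The authors deposited 3 tables of raw counts, per the file headers: back-splice junction reads for 3503 circRNAs, reads for 11374 protein-coding genes and reads for 595 lncRNA rows. The lncRNA rows repeat a transcript for each associated gene, with equal counts, and were reduced to 431 transcripts. The circRNA table also holds the authors' log2 CPM from edgeR, per the file headers, in which every count of 0 has the same value. They were read for comparison and no printed value rests on them. The 12 normalized per-library columns of the gene and lncRNA tables were not used. The submitters' processing notes name CASAVA 1.8, BWA and the human build hg19. The circRNA caller, the read counter, its strand setting and the annotation are not given in the sources used here. The circRNA coordinates run over chromosomes up to 29 and scaffolds named LWLT, so they are printed as deposited with no build. Starts were converted to count from 1.

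Of 11374 genes, 2223 have no symbol and are given by identifier. The RefSeq gene table of assembly ARS1.2 was matched on its gene number and used only to find which genes lie next to each other. It placed 8451 genes, of which 1651 were tested. Genes on unplaced scaffolds and on the X chromosome were left out because the table names no scaffold. A neighbour is another RefSeq gene that overlaps or lies within 1 kb on either strand.

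Each table was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest), with the total of the table as library size and Benjamini-Hochberg adjustment at 0.05. The filter kept 2148 genes, 98 lncRNAs and 22 circRNAs. Standard errors are the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. Where a group had 0 reads the fold is a bound against 3 reads over the group's 3 libraries, and with 1 to 3 reads it is a ratio with a 95% exact counting interval. Intervals and bounds cover counting error only, and reads of 1 fragment are not independent. In simulations with the real means, spread and library sizes, 25.6% of genes changed 2-fold and 90.7% of genes changed 4-fold were recovered (2148 genes). For 98 lncRNAs this was 12.8% and 76.8%, and for 22 circRNAs 23.3% and 94.2%, so changes of 2-fold were mostly out of reach. With 4-fold changes 4.93% of gene, 3.46% of lncRNA and 8.87% of circRNA calls were false, the last above what the threshold of 0.05 aims at.

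Before the data were examined, 34 gene lists were fixed, and the 14 with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation 0.01), beside an estimated correlation and fry. Named features followed a rule fixed at the same time. It took the 10 largest increases and decreases among named genes past the threshold whose groups did not overlap and whose higher group reached 5 CPM, and up to 4 passing members per list or, with none, the 2 most abundant. It also took the 5 largest lncRNA and 8 largest circRNA changes in each direction without overlap, the 5 most abundant circRNAs, and 10 genes given whatever their change. Some features this rule took are not reported here, and counts include them. Detected circRNAs and junction totals were compared by exact two-sided permutation over 20 assignments, whose smallest p is 0.1. Thinning drew 200 random subsets of 1289 reads per library. Python 3.11.15, scipy 1.17.1 and pandas 2.3.3 were used.

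Alternatives were DESeq2 size factors, no scaling factor, no filter, a mean count of at least 10, the DESeq2 1.42.0 Wald test, other thresholds with a 2-fold change, the replicate number as a block, and leaving out each library. Added after the data were seen were scaling of circRNAs by the gene table, list tests with no scaling factor, the intergenic share without the most abundant circRNA, fits without the most counted features (for lncRNAs also with no scaling factor), and genes without a neighbour, scaled on their own. The intergenic share without the most abundant circRNA kept that circRNA in the total of junction reads. Alternatives for normalized values did not apply to counts.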

Results

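Circular RNAs, protein-coding genes and long noncoding RNAs (lncRNAs) were counted in goat (Capra hircus) fetal fibroblasts, the connective tissue cells that make and remodel the extracellular matrix, labelled with a fetal age of 50 days. Treated cells were kept for 10 weeks in medium with 0.5 µg/mL of a nanocomposite of graphene oxide and silver nanoparticles (GO-AgNP), and control cells were kept without it. There were 3 libraries in each group, all made from ribosomal RNA-depleted total RNA with a kit that records the strand. The gene table held 218493, 155452 and 160571 reads in treated replicates 1 to 3 and 203786, 245958 and 203790 reads in the controls. The lncRNA table held 23491, 15888 and 21886 reads in the treated and 4970, 5541 and 4959 reads in the control libraries. Back-splice junction reads, which cross the joint where a circular RNA is closed, numbered 1412, 1289 and 1586 in the treated and 5597, 6944 and 4807 in the control libraries. The labels do not say that the libraries of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical.

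A few features took much of the reads. The gene ENSCHIG00000018556, which carries no symbol, took 37.4% ± 8.94 of the treated gene reads against 8.18% ± 5.66 of the control gene reads (SD, n = 3 each; exact two-sided permutation test p = 0.1, the smallest that 3 against 3 allows). The 974-nt intergenic lncRNA ENSCHIT00000005061 took 91.7% ± 1.46 of the treated lncRNA reads against 12.6% ± 11.7 of the control lncRNA reads (SD, n = 3 each; exact two-sided permutation test p = 0.1). The gene was singled out after its values were seen. Among named genes the order of abundance was unusual. ND6, the mitochondrial gene encoded on the strand opposite to COX1, had 13.7 to 96.4 times the reads of COX1 in the 6 libraries. Of the 100 named genes with the most control reads, 75 had another RefSeq gene overlapping them or within 1 kb, against 47.7% of the other 8351 named genes with a known position. Neither the counter nor its strand setting is given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand therefore cannot be told apart in the values that follow. If reads were assigned to the opposite strand, a gene's sense transcript would be counted only through reads recorded on the wrong strand, also without a neighbour. COL1A1, FN1 and COL1A2 have no neighbour and were among the 20 most counted named genes, with 3744, 2533 and 2367 control reads. The share of wrong-strand reads, and whether it differed between the groups, was not tested. A gene said to rise or fall did so in counted reads, which may not be its mRNA level.

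The first comparison asked which circular RNAs differ after the chronic exposure. Fewer circRNAs were detected in treated cells. A treated library had 505.3 ± 72.3 circRNAs with at least 1 junction read and a control library 1767 ± 187.1 (SD, n = 3 each), a ratio of 0.286. Junction reads numbered 1429 ± 149.2 per treated and 5783 ± 1081 per control library, a ratio of 0.247. The exact two-sided permutation test gave p = 0.1 for both, the smallest that the 20 assignments of 3 against 3 libraries allow, and the highest treated library lay below the lowest control library. Set against the gene table, the treated libraries had 949.9 ± 54.1 and the controls 2247 ± 73.5 junction reads per 100000 scaled gene reads (SD, n = 3; exact permutation test p = 0.1), a scaling chosen after the totals were seen. No total of sequenced or mapped reads was used here, so these ratios are not corrected for sequencing depth. Gene reads do not stand in for it, since their strand assignment is in doubt. When every library was thinned to 1289 junction reads, 480.6 ± 46.2 circRNAs remained in the treated and 713.2 ± 10.3 in the control libraries (SD, n = 3; exact permutation test p = 0.1).

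**Figure D1:**
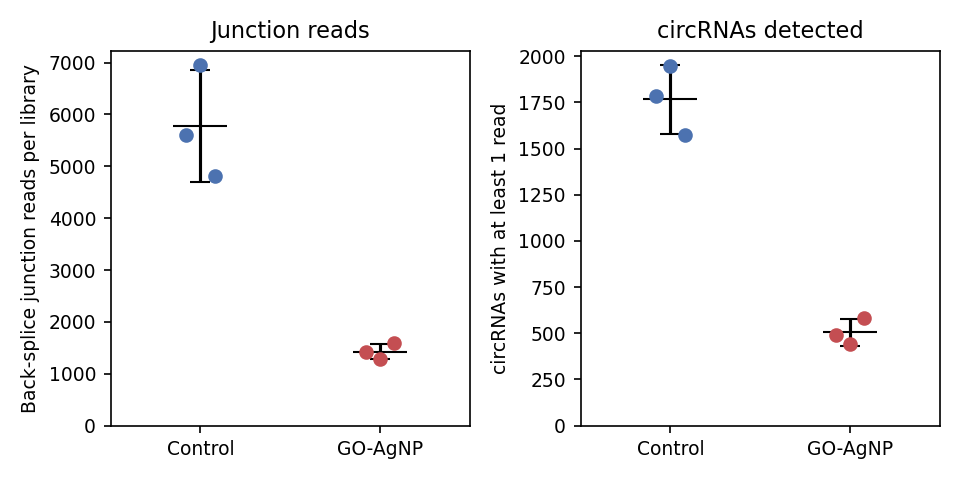
Back-splice junction reads per library (left) and circRNAs with at least 1 junction read per library (right) in the 3 control and 3 GO-AgNP libraries. Points are libraries, horizontal bars the means and whiskers the SD. The treated libraries lie between 1289 and 1586 reads and between 440 and 583 circRNAs, all below the control libraries.

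The circRNA sets of the groups overlapped little. Of 3503 circRNAs listed, 913 had a junction read in any treated and 2847 in any control library, and 257 were seen in both groups. All 3 control libraries shared 689 circRNAs and all 3 treated libraries shared 147, and 32 were present in all 6. With at least 10 reads in a group and none in the other, 190 circRNAs were seen in control libraries and 32 in treated libraries. These counts are not corrected for depth, and treated libraries had 0.247 times the junction reads of controls. The same minimum is therefore harder to reach in treated cells, and a lack of reads there says less about absence. Exonic circRNAs, whose ends lie at annotated exons, made up 61.1% of those listed, and sense overlapping ones 18.4%. Antisense circRNAs took 9.37% ± 0.973 of the treated and 4.50% ± 0.509 of the control junction reads, and intergenic ones 16.1% ± 0.754 and 21.6% ± 1.17 (SD, n = 3). An alternative added after the data were seen took the most abundant circRNA out of the intergenic reads but kept it in the total. The intergenic share then turned to 6.70% ± 0.540 in treated and 4.72% ± 0.128 in control libraries (SD, n = 3; exact permutation test p = 0.1). Exonic ones took 47.0% ± 2.15 and 51.6% ± 0.905, sense overlapping ones 22.5% ± 1.74 and 18.6% ± 0.324, and intronic ones 5.06% ± 0.747 and 3.69% ± 0.838 (SD, n = 3). The exact two-sided permutation test gave p = 0.1 for each category except intronic, at p = 0.2.

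At this depth 22 circRNAs passed the low-count filter, and 10 rose and 5 fell in treated cells past an edgeR adjusted p of 0.05. The filter scaled its minimum of 10 to library totals, so fewer reads were needed in a treated than in a control library. The PDE5A circRNA passed with 5, 5 and 5 treated reads and none in the controls. The 10 against 5 is therefore no balance of directions. Those that rose included circRNAs from PRRC1, PIK3R1 and KAT7, each without a junction read in the controls. The PRRC1 circRNA (exonic, chromosome 7, 84193926 to 84207218, plus strand) had 14, 10 and 21 treated reads and was at least 42.4-fold higher (adjusted p = 0.000909). PIK3R1 encodes a regulatory subunit of phosphoinositide 3-kinase, and its intronic circRNA (chromosome 20, 11474578 to 11474795, minus strand) had 14, 12 and 13 treated reads, at least 36.8-fold higher (adjusted p = 0.000178). The exonic circRNA of KAT7, a histone acetyltransferase (chromosome 19, 36471752 to 36473897, minus strand), had 12, 11 and 13 treated reads and was at least 33.9-fold higher (adjusted p = 0.000178). These bounds set a group at 0 to 3 reads over its 3 libraries. Also past the threshold were circRNAs of PDE5A (at least 14.1-fold higher), of the unnamed gene ENSCHIG00000007336 (at least 36.8-fold), of KANSL1 (log2 fold change 4.74 ± 0.91 SE) and of ZNF532, with 18 treated reads and 1 control read (50.9-fold, 95% counting interval 8.04 to 2121).

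The 5 circRNAs that fell came from OAS1, NAB1, TENT4A and BNC2 and from an intergenic locus. The OAS1 circRNA (intronic, chromosome 17, 9759064 to 9766303, plus strand), from a gene of the interferon-induced antiviral response, had 30, 40 and 31 control reads and none in the treated libraries, at least 11.9-fold lower (adjusted p = 0.000734). The exonic NAB1 circRNA (chromosome 2, 130861551 to 130862388, plus strand) had 24, 34 and 18 control reads and none in treated cells, at least 8.96-fold lower (adjusted p = 0.00202). The exonic TENT4A circRNA (chromosome 20, 66422777 to 66426883, minus strand) had 66 control and 2 treated reads, 11.7-fold lower with a counting interval of 3.11 to 98.4. The exonic circRNA of BNC2, which encodes a zinc finger protein (chromosome 8, 27805904 to 27807873, plus strand), changed by a log2 of -1.53 ± 0.37 SE (adjusted p = 0.0105), a call lost with a mean of at least 10 reads required (log2 -1.10, adjusted p = 0.143). The most abundant circRNA, intergenic on scaffold LWLT01000027.1 (6635395 to 6636857, minus strand), had 974, 1090 and 849 control and 132, 119 and 153 treated reads, a log2 fold change of -1.37 ± 0.13 SE (adjusted p = 0.000263). No build is given for these coordinates in the sources used here. Among the other most abundant circRNAs, one antisense to HDAC11 (chromosome 22, 58305714 to 58404500) was higher (log2 1.11 ± 0.22 SE, adjusted p = 0.00453), while circRNAs of ENSCHIG00000011093 (log2 -0.19 ± 0.16 SE) and ENSCHIG00000023592 (log2 -0.39 ± 0.29 SE) did not pass. These changes and bounds are relative to a TMM scaling computed on the 22 tested circRNAs, which held 27.6% of the junction reads. With no scaling factor beyond the library total, 14 rose and 5 fell. The most abundant circRNA took 9.41% ± 0.214 of the treated and 16.9% ± 1.07 of the control junction reads (SD, n = 3). That is a smaller fall than its scaled fold change. Scaled by the gene table instead, 8 rose and 7 fell: the HDAC11 circRNA no longer passed (log2 0.40, and 0.54 without a filter) and those of ENSCHIG00000011093 (log2 -0.90) and ENSCHIG00000023592 (log2 -1.12) fell, and with no scaling factor the ENSCHIG00000011093 value was 0.34 and passed as higher. With a mean of at least 10 reads required, 13 were tested, of which 1 rose and 4 fell. Predicted lengths were 98787 nt for the HDAC11 circRNA, 79038 nt for that of ENSCHIG00000011093 and 79832 nt for that of ENSCHIG00000007336. Whether junctions this far apart come from single circular RNAs was not tested.

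**Figure D2:**
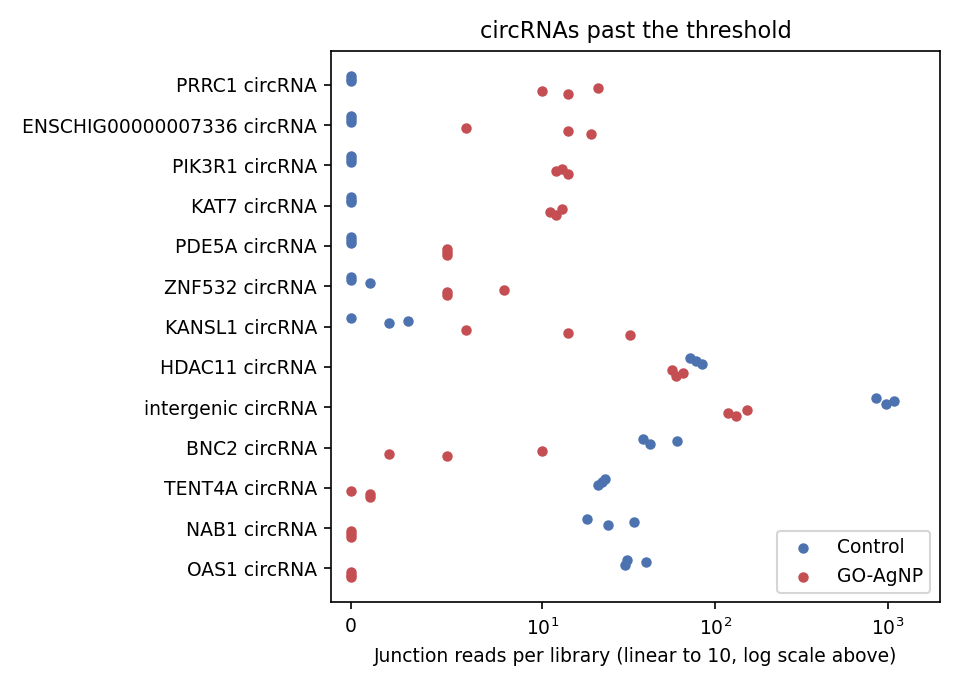
Junction reads per library (horizontal axis, linear to 10 and logarithmic above) of 13 circRNAs past the threshold, by host gene. Each point is 1 of the 3 control or 3 GO-AgNP libraries. The OAS1 and NAB1 circRNAs have no treated reads, and those of PRRC1, ENSCHIG00000007336, PIK3R1, KAT7 and PDE5A have no control reads.

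Whether a circRNA moved with the gene it comes from could be asked for 6 circRNAs whose host gene was also tested. Across them, which are not independent replicates, Spearman's rho was -0.60 (exact permutation test p = 0.242, n = 6). The OAS1 circRNA had no treated reads while OAS1 gene reads rose from 34.8 ± 6.51 to 179.1 ± 27.3 CPM (SD, n = 3; log2 2.34 ± 0.42 SE, edgeR adjusted p = 9.18e-05). PDE5A went the other way, with its circRNA present in treated libraries alone and a gene that fell by 3.78 on the log2 scale (edgeR adjusted p = 3.2e-05). BNC2 gene reads had a log2 fold change of 0.71 that did not pass (adjusted p = 0.221), beside a lower circRNA.

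The second comparison asked which genes differ between exposed and control cells. Of 2148 genes tested, 534 rose and 574 fell in treated cells past an edgeR adjusted p of 0.05. With no scaling factor beyond the library total, 326 rose and 769 fell, because the median log2 fold change of all genes then moved from -0.02 to -0.47, and changes are reported relative to the scaled median. Treated and control libraries did not overlap for 58.8% of the tested genes, where chance gives 10%. Without any low-count filter 941 genes rose and 1165 fell. Tested genes with a RefSeq neighbour within 1 kb had a median log2 fold change of -0.24, with 217 that rose and 324 that fell of 1037, and those without one 0.47, with 219 that rose and 104 that fell of 614. In a fit of these 614 genes alone, an alternative added after the data were seen, 140 rose and 151 fell, because its own scaling moved their median log2 fold change from 0.47 to -0.01.

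The largest increases were in genes with no or few control reads. TLX2, a homeobox transcription factor, had 22, 10 and 25 treated reads and none in the controls, at least 32.4-fold higher. SLC23A1, a vitamin C transporter, was at least 31.9-fold higher, the intramembrane protease SPPL3 at least 29.6-fold, the autophagy factor ATG13 at least 25.0-fold, and MAP3K14, the kinase of noncanonical NF-kB signalling, at least 24.5-fold. MPP1, NXF1 and SALL2 also had no control reads, with bounds of 22.8, 20.5 and 19.9. CUX1 had 63 treated reads and 1 control read and CRY1, a repressor of the circadian clock, 102 and 2 (87.1-fold, counting interval 23.5 to 729). The 10 largest decreases were EFNA1, ZNRD2, ZSCAN16, ABCA6, LPAR6, PTPRQ, ACOT7, IFIH1, SLC26A1 and ZFP30, all with no treated reads. EFNA1, a membrane-bound ligand of Eph receptors, had 19, 37 and 20 control reads, at least 14.8-fold lower, and LPAR6, a lysophosphatidic acid receptor, 12, 27 and 18, at least 11.1-fold lower. None of the 89 genes named by the fixed rule changed sign where the main fit or the alternative passed, among the alternatives that tested it. SLC23A1, ATG13, NXF1, CUX1 and CRY1 among the increases, and EFNA1, ZSCAN16, LPAR6, ACOT7 and SLC26A1 among the decreases, have a RefSeq gene within 1 kb.

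Members of the gene lists fixed before the data were examined are counted as higher, lower or not past the threshold over all genes tested. Adjusted over the list alone the counts were the same, except for contractile genes (11 higher and 1 lower), lipid synthesis (1 higher) and histones (2 higher).

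Collagens rose. Of 12 collagen genes tested, 10 rose, none fell and 2 did not pass, and the list's median log2 fold change was 1.08. COL4A2 and COL4A1, the paired chains of basement membrane collagen, were 4.61-fold (log2 2.21 ± 0.22 SE) and 3.68-fold higher, and COL6A2 and COL16A1 3.92-fold and 2.95-fold. COL1A1, the main chain of fibrillar collagen, went from 4873 ± 225.0 to 10402 ± 1050 CPM (SD, n = 3; log2 1.09 ± 0.14 SE, edgeR adjusted p = 2.49e-06). As a set the collagens stood above the other genes (camera, adjusted p = 1.76e-06 at a preset inter-gene correlation of 0.01), but not with an estimated correlation (adjusted p = 0.36). Among genes without a neighbour the camera adjusted p was 0.0468.

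Of 17 contractile and TGF-beta response genes tested, 8 rose, 1 fell and 8 did not pass. LTBP2, which binds fibrillin in the matrix, was 7.32-fold higher (log2 2.87 ± 0.39 SE), the smooth muscle actin ACTG2 5.33-fold, the tropomyosin TPM2 rose by log2 1.68 ± 0.22 SE and the actin-binding CALD1 was 2.87-fold higher (log2 1.52 ± 0.19 SE). The set's camera adjusted p was 0.0150. It was 0.36 with an estimated correlation, 0.31 among genes without a neighbour and 0.112 without a filter. With the filter no other of the 14 lists tested passed by camera, and none passed with an estimated correlation. Without a filter the interferon and mitochondrial lists passed too.

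**Figure D3:**
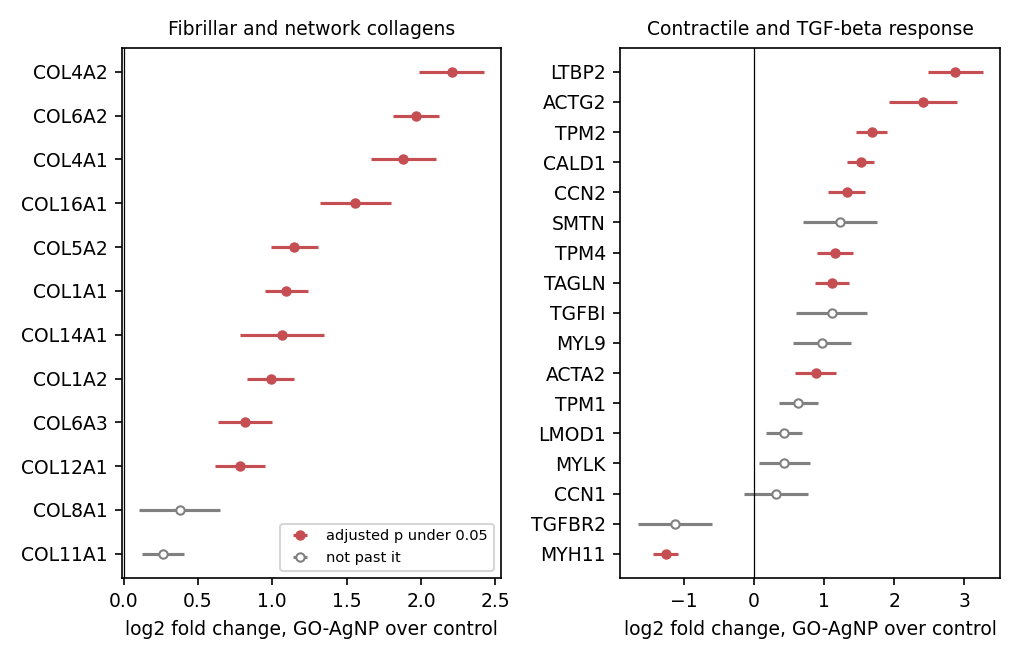
Log2 fold change of each tested collagen gene (left, 12 genes) and contractile or TGF-beta response gene (right, 17 genes) in GO-AgNP over control cells. Points are edgeR estimates from 3 libraries per group, bars are the SE, and filled points have an adjusted p under 0.05. All 10 collagens past the threshold lie above 0, and 8 of 9 contractile genes past it do.

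Other matrix genes went both ways. Of 24 matrix glycoproteins and proteoglycans tested, 11 rose, 4 fell and 9 did not pass (camera adjusted p = 0.122). Tenascin C (TNC) was 11.8-fold and EMILIN1 10.9-fold higher, while asporin (ASPN) and nidogen (NID1) were 6.31-fold and 5.44-fold lower. Of 7 matrix proteases and inhibitors, 2 rose, 2 fell and 3 did not pass. TIMP2 rose by log2 1.09, and TIMP1 and CTSK fell by 1.87 and 1.24 on the log2 scale. The TIMP1 call was lost without treated replicate 1 or 3 or control replicate 1 or 2 (adjusted p 0.0696 to 0.137), with a mean of at least 10 reads (adjusted p = 0.0610) and by the DESeq2 Wald test (adjusted p = 0.0681), and that of CTSK without control replicate 3 (adjusted p = 0.0657). Of 5 fibroblast markers 2 rose and 3 did not pass, with a median log2 fold change of -0.27, a mean of 0.25 and a camera direction upward (adjusted p = 0.597). VIM rose 2.01-fold (log2 1.01 ± 0.18 SE, edgeR adjusted p = 7.84e-05) and NT5E 3.54-fold, whereas PDGFRA had a log2 fold change of -0.91 ± 0.43 SE that did not pass (adjusted p = 0.0813).

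Genes of protein folding in the endoplasmic reticulum were higher where they passed. Of 7 unfolded protein response genes, 4 rose and 3 did not pass. PDIA6 was 5.88-fold, the chaperone HYOU1 5.46-fold, HSPA5 (BiP) 2.82-fold (log2 1.49 ± 0.25 SE, edgeR adjusted p = 3.65e-05) and CALR 1.51-fold higher. The list's camera adjusted p was 0.103. PDIA6 and HYOU1 have a neighbour within 1 kb, and HSPA5 and CALR do not. The CALR call was lost without treated replicate 1 or control replicate 1 or 2 (adjusted p 0.0501 to 0.140), by the DESeq2 Wald test (adjusted p = 0.0511), without a filter (log2 0.33, adjusted p = 0.363) and in the fit of genes without a neighbour (log2 0.12, adjusted p = 0.686), whose scaling lowers all its fold changes as given above. DDIT4 (log2 2.57 ± 0.57 SE) and SHMT2 (log2 1.53 ± 0.57 SE) rose among 3 genes of the ATF4 amino acid response, and HSP90AA1 was the heat shock gene that rose, 2.42-fold, of 3 tested. SHMT2 did not pass without treated replicate 1 or 2 or control replicate 1 or 2 (adjusted p 0.0743 to 0.136), nor without a filter (adjusted p = 0.115).

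Few metal and oxidative stress genes reached the depth for a test. FTH1, the ferritin heavy chain, was the single metal handling gene tested and rose 1.45-fold (adjusted p = 0.0390), a call that held only without treated replicate 3 when 1 library was left out (adjusted p 0.0520 to 0.167 for the others). FTH1 was also lost by the DESeq2 Wald test (adjusted p = 0.0649) and without a filter (log2 0.27, adjusted p = 0.449). Of 4 NRF2 targets, TALDO1 and FTH1 rose, NQO1, a quinone reductase, fell from 196.5 ± 23.7 to 54.2 ± 37.9 CPM (SD, n = 3; log2 -1.83 ± 0.43 SE, edgeR adjusted p = 0.00131), and PGD did not pass. The TALDO1 call was lost without treated replicate 2 or control replicate 2 or 3 (adjusted p 0.0508 to 0.0662) and without a filter (adjusted p = 0.0666). GPX3, a secreted glutathione peroxidase and the antioxidant enzyme tested, rose 3.61-fold, a call lost without treated replicate 1 (adjusted p = 0.0526). HMOX1 was too low to test, with 11, 0 and 2 treated and 10, 8 and 7 control reads, and MT2A was not analysed here.

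Of 8 interferon-stimulated genes tested, 5 fell, 1 rose and 2 did not pass (camera adjusted p = 0.185, and 0.0210 without a filter). MX1, an antiviral GTPase, was 15.6-fold lower (log2 -3.96 ± 0.59 SE, edgeR adjusted p = 1.17e-05), IFIT1 3.63-fold lower (not past the threshold without treated or control replicate 1, adjusted p 0.0501 and 0.0701), and IFIH1, a sensor of double-stranded RNA, at least 9.96-fold lower. OAS1 rose, as above. The cytokine IL6 fell by 1.44 on the log2 scale and CSF1 rose by 2.04, of 3 inflammatory genes tested.

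The 3 tested cell cycle genes fell: KIF20A by 1.30, CCNE2 by 1.25 and MCM7 by 1.22 on the log2 scale (MCM7 SE 0.17, edgeR adjusted p = 6.52e-06), and each has a neighbour within 1 kb. KIF20A did not pass without treated replicate 1 or 3 (adjusted p 0.0607 and 0.0661), and CCNE2 passed only without treated replicate 1 when 1 library was left out (adjusted p 0.0551 to 0.174 for the others). CCNE2 was also lost with DESeq2 size factors (adjusted p = 0.0521), a mean of at least 10 reads (adjusted p = 0.0831) and the DESeq2 Wald test (adjusted p = 0.0955). Of 5 p53 targets, TP53I3, SESN1 and DDB2 fell by 2.52, 2.06 and 1.06 and 2 did not pass (camera adjusted p = 0.185). These 3 genes have neighbours within 1 kb too. Of 5 DNA repair genes 1 fell and 4 did not pass, and neither MCL1 nor BAD, the 2 apoptosis regulators tested, passed (BAD did without control replicate 1, adjusted p = 0.0373). Of 4 senescence genes 2 rose, among them IGFBP7 (log2 1.57 ± 0.37 SE), 1 did not pass and RBL2 fell. MKI67 was not analysed here. Of 3 autophagy genes ATG13 rose and 2 did not pass, and of 2 histone genes H1-4 rose 2.26-fold.

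Metabolic genes were mixed. Of 17 hypoxia and glycolysis genes, 7 rose, 2 fell and 8 did not pass (camera adjusted p = 0.126). PFKL was 5.33-fold, TPI1 4.21-fold, VEGFA 3.22-fold (log2 1.69 ± 0.25 SE) and PKM 2.74-fold higher. Of 7 genes of sterol and fatty acid synthesis 2 rose and 5 did not pass. ACLY, which makes acetyl-CoA for lipid synthesis, rose by log2 2.62 ± 0.57 SE. Of 12 mitochondrial genes, 5 fell and 7 did not pass: ND1 was 8.21-fold lower, ND6 3.75-fold (log2 -1.91 ± 0.16 SE, edgeR adjusted p = 1.25e-08), CYTB 2.97-fold and COX3 1.56-fold (camera adjusted p = 0.112, and 0.00279 without a filter). NDUFS3, the nuclear respiratory chain gene tested, fell by 2.27. COX3 did not pass without treated replicate 2 or 3 or control replicate 1 (adjusted p 0.0667 to 0.0680), nor NDUFS3 without treated replicate 1 or 2 (adjusted p 0.0509 and 0.0521). Of 15 ribosomal protein genes, RPL27, RPLP2 and RPLP0 rose 2.89-, 2.82- and 2.27-fold and 12 did not pass. RPL27 was lost without control replicate 2 or 3 (adjusted p 0.0571 and 0.0505) and RPLP0 without treated replicate 1 (adjusted p = 0.0771). Both were also lost without a filter (adjusted p 0.103 and 0.0589) and, by the same lowering, in the fit of genes without a neighbour (log2 1.06 and 0.70, adjusted p 0.0994 and 0.127).

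Of 7 tested regulators of circular RNA formation or turnover, 3 rose and 4 did not pass (camera adjusted p = 0.307). KHSRP was 2.58-fold higher (log2 1.37 ± 0.55 SE, edgeR adjusted p = 0.0417) and ESRP2 1.97-fold. KHSRP did not pass without treated replicate 1 or 2 or control replicate 2 or 3 (adjusted p 0.0505 to 0.184), nor ESRP2 without treated replicate 1 or control replicate 2 or 3 (adjusted p 0.0989 to 0.135). Both were also lost without a filter (adjusted p 0.173 and 0.242) and by the DESeq2 Wald test (adjusted p 0.0659 and 0.0631). ADAR had a log2 fold change of -0.40 ± 0.53 SE and did not pass (adjusted p = 0.545). QKI had 0, 2 and 0 treated and 7, 8 and 6 control reads, and DHX9 0, 2 and 2 against 2, 2 and 0, too few to test. Markers of other cell types were hardly counted. No epithelial, endothelial, adipocyte, neural or erythroid marker could be tested. CSF1R, a macrophage marker, rose 2.21-fold, RUNX2, a bone regulator, fell by 1.93 on the log2 scale, and CKM, of skeletal muscle, did not pass (adjusted p = 0.134; 0.00808 without control replicate 2). CSF1R was lost without treated replicate 3 or control replicate 1 (adjusted p 0.0510 and 0.0526) and without a filter (adjusted p = 0.105), and RUNX2 without treated replicate 1 or control replicate 2 (adjusted p 0.0682 and 0.0761). With no scaling factor the increases of FTH1, TALDO1, CALR, SHMT2, TIMP2, RPL27, RPLP0, KHSRP, ESRP2, VIM and CSF1R did not pass, and MCL1 and PDGFRA passed as lower (log2 -0.88 and -1.39), as they did in the fit of genes without a neighbour (log2 -0.89 and -1.39), whose scaling lowers fold changes by about as much.

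The third comparison asked which lncRNAs differ. Of 98 lncRNAs tested, 11 rose and 30 fell in treated cells past an edgeR adjusted p of 0.05. The filter scaled its minimum of 10 to library totals, which ENSCHIT00000005061 raised in the treated libraries. More reads were therefore needed in a treated than in a control library, and the 11 against 30 is no balance of directions. With a mean of at least 10 reads 15 rose and 17 fell of 63, and without a filter 25 rose and 43 fell of 431. ENSCHIT00000005061 had 21887, 14338 and 20080 treated and 523, 117 and 1255 control reads (log2 6.46 ± 1.57 SE, adjusted p = 0.000490). The next increases were the intergenic ENSCHIT00000008149 (log2 3.53 ± 0.54 SE) and ENSCHIT00000027731 (log2 2.93 ± 0.37 SE), the 342-nt ENSCHIT00000004597 divergent to PARP2 (log2 2.19 ± 0.21 SE, adjusted p = 8.90e-21) and ENSCHIT00000009525 antisense to an intron of PPP2R2B (log2 2.06 ± 0.68 SE). These 4 turned negative with no scaling factor, at log2 -0.13, -0.75, -1.49 and -1.55. That setting called 1 lncRNA higher and 95 lower, since its median log2 fold change was -3.95 against -0.28, so apart from ENSCHIT00000005061 directions hold relative to the other lncRNAs. The largest decreases were antisense to introns of SBF2, RORA, MACROH2A1 and CYP7B1, with 59, 47, 39 and 34 control reads, and the intergenic ENSCHIT00000005480 with 33, all without treated reads and at least 5.93-, 4.72-, 3.92-, 3.42- and 3.32-fold lower. Without control replicate 1 the number that rose was 6, and without control replicate 2 it was 7, and in both ENSCHIT00000009525 did not pass (adjusted p 0.0977 and 0.0713), nor did it without a filter (adjusted p = 0.0813).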

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

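The gene-table scaling of circRNAs, the intergenic share without the most abundant circRNA, the list tests with no scaling factor, the fits without the most counted features and the genes without a neighbour were chosen after the data were seen. DESeq2 size factors, the DESeq2 Wald test and both 2-fold thresholds kept every count of calls within 1.5 times its main value. With no scaling factor 326 genes rose, 1 lncRNA rose and 95 fell. That setting reversed 4 named lncRNAs, to -0.13, -0.75, -1.49 and -1.55, and the circRNA of ENSCHIG00000011093, to 0.34. One lncRNA took 91.7% of the treated lncRNA reads. Without it, of the 97 others that the same filter had kept, 10 lncRNAs rose and 33 fell. With no scaling factor either, 8 rose and 34 fell. None of the named lncRNAs then reversed, so the lncRNA shift came from its reads in the totals. With the most abundant circRNA taken out of the intergenic reads but kept in the total, the intergenic share, treated over control, reversed from 0.744 to 1.42. With no filter 941 genes rose and 1165 fell, 25 lncRNAs rose, and 24 circRNAs rose and 11 fell, since more features were tested. A mean count of at least 10 left fewer features, with 17 lncRNAs lower and 1 circRNA higher. It counts raw reads, whereas the main filter scales its minimum to library totals, so they select features of each group differently. Genes without a neighbour, a smaller set with its own scaling, gave 140 higher, 151 lower (219 and 104 of the same genes in the main test) and 1 list past the threshold. An estimated correlation left 0 lists (against 2), and fry, which asks another question, gave 10. Leaving out each library gave 449 to 548 genes higher and 475 to 537 lower, 6 to 13 lncRNAs higher and 20 to 27 lower, 9 to 10 circRNAs higher and 5 lower, and 2 lists each time. The ratio of detected circRNAs ranged from 0.264 to 0.304, that of junction reads from 0.228 to 0.275, and rho from -0.60 to -0.49.

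The labels do not say that equal replicate numbers pair the libraries. Same-number deviations correlated at -0.02, -0.01 and -0.03 for genes, 0.13, -0.01 and -0.02 for lncRNAs and 0.38, -0.12 and 0.19 for circRNAs. No table had all 3 above 0.1. Libraries of different number correlated at -0.46 to 0.15 for circRNAs. With 3 libraries per group these values cannot exclude pairing. With the replicate number as a block 497 genes rose and 544 fell, 9 lncRNAs rose and 23 fell, 10 circRNAs rose and 5 fell, and 2 lists passed. FTH1, SHMT2, CCNE2, NDUFS3, KHSRP and ESRP2 did not pass with it (adjusted p 0.0501 to 0.0749).

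Of the 1171 values of named genes under alternatives, 1072 stayed on their side of the threshold, 93 lost it, 6 gained it and 0 reversed. A change of sign was counted as reversed only where the main or the alternative value passed. Depth limits the circRNA test: 22 of 3503 circRNAs passed the filter.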

Other observations

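The equal-depth sharing of circRNAs and the ratio of ND5 to COX1, COX2 and COX3 were tests chosen after the result was seen, as were the limit of the neighbour tests to placed chromosomes, the reference for even counts in the test of repeat draws and the comparison of gene dispersion by read number.

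Collagen genes hosted 17 circRNAs with 105 junction reads in control cells and 4 with 6 reads in treated cells, 0.584% ± 0.194 against 0.136% ± 0.0560 of the junction reads (SD, n = 3; exact two-sided permutation test p = 0.1, the smallest possible). In gene reads, 10 of 12 tested collagen genes rose. These are not matched gene by gene: the circRNAs came from 6 collagen genes, and COL12A1 gave 49 of the control junction reads. No collagen was among the circRNAs compared with their host gene. Interferon-stimulated genes hosted 8 circRNAs with 133 control reads and none in treated cells, 112 of them from OAS1, whose gene reads rose (log2 2.34), while 5 of 8 such genes fell in gene reads. Targets of p53 hosted 3 circRNAs with 17 control reads and none in treated cells. Of 34 lists compared, those of the unfolded protein response, heat shock and p53 reached the same p with a lower share in treated cells. They held 3 circRNAs each, with 13, 10 and 17 control reads and no treated reads. Of 2847 circRNAs seen in controls, 2590 had no treated read, so such absence is not particular to these lists or the interferon list. NRF2 targets and lipid synthesis reached the same p with a higher share, each resting on 1 circRNA seen in treated cells. AHNAK, a very large scaffold protein gene, hosted the most circRNAs, 18, of which 16 were seen in control and 3 in treated cells. CEMIP, which takes part in hyaluronan breakdown, hosted 12, with 77 control reads and 1 treated read. Both hosts were picked after their values were seen.

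Junction reads came mostly in even numbers. Among circRNAs with at least 2 reads in a library, 75.6% to 84.4% had an even count in each of the 6 libraries, and 827 circRNAs had 2 reads in total against 713 with 1. Of such counts for genes, 62.4% to 64.0% were even.

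Reads counted to genes do not follow the known order of abundance: ND6 lay above COX1 in all 6 libraries. Correct counting on the annotated strand is argued against by other genes: ND5, on the strand of COX1 and known to be less abundant, had at least 11.2 times the reads of COX1, COX2 and COX3 together in each library. Reads assigned to the strand opposite to the gene are a candidate explanation. It predicted that the most counted named genes have close neighbours more often, and the odds ratio was 3.29 (95% interval 2.07 to 5.42). Neighbours on either strand were counted, and ND6, ND5 and ND4, with mitochondrial neighbours, were among the most counted genes. Whether correct counting also gives such an odds ratio was not tested, so it does not single out the opposite strand. The kit records strand, so an opposite setting in the counting is possible, but no biological explanation was tested.

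The count of genes that rose or fell, 1108, has a technical candidate beside the exposure itself. Leaving out the 2 most counted genes gave 1110, but TMM trims such genes already and the median log2 fold change moved only from -0.02 to -0.01, so distorted scaling stays open, and with no scaling factor 326 genes rose and 769 fell. A different share of reads from neighbouring genes in the groups predicted lower fold changes for genes with a neighbour, and the medians differed by -0.70 (95% interval -0.90 to -0.50). Part of the changes, those of collagen, cell cycle and p53 genes included, may therefore reflect how reads were assigned. Of 614 genes without a neighbour 219 rose and 104 fell, but this restates the same difference of medians. Scaled on their own, 140 of them rose and 151 fell, so the count cannot weigh against this explanation. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave 1108 genes, 41 lncRNAs and 15 circRNAs, as many as 1 of 10 splits in each table, and the highest of the other splits gave 0 in each.

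The groups share few circRNAs, and lower depth of the treated libraries is argued against: at equal junction reads, pairs from different groups shared 0.287 times as many circRNAs as pairs within a group, where a simulation from 1 pool gave 1.01. Chimeric cDNA formed in the library reaction predicted a sharing ratio at least 2 times higher for exonic circRNAs than for intronic, antisense and intergenic ones, and it was 1.54 times (95% interval 0.996 to 2.91), which leaves it open. Libraries of a group that are repeat draws from 1 RNA pool would share by origin, and the pooled index of dispersion of circRNAs within groups was 2.83 (95% interval 1.93 to 4.16). Even counts put such draws at up to 2, not at 1 as first assumed. Which value up to 2 applies was not tested, so the index does not decide. Counting noise alone predicted the same median index for genes with at least 200 reads as for genes with 20 to 200: it was 3.31 times as high in treated libraries (95% interval 2.04 to 4.48), which argues against it there, and 1.45 times in controls (95% interval 1.08 to 1.75), short of the bound of 1.1. Preparing libraries adds spread of its own, so 1 RNA pool cannot be told apart from separate cultures, and an effect of the exposure stays open.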
